A study of Mus musculus with 4 samples.

How the data were processed

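RNA from 4 populations of mouse intestinal tumour cells was measured on 4 one-colour (Cy3) Agilent gene expression arrays, 1 array per population. Per the labels, epithelial tumour cells carrying the surface protein EpCAM were taken 14 days after tamoxifen from Lgr5-CreERT2 mice with a loxP-flanked exon in both copies of Ctnnb1, the gene for beta-catenin. The cells were divided by the stem cell receptor Lgr5 and by a tuft cell marker, which the design text names as IL17RB, into Lgr5+ tuft marker+, Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker- cells. Per the labels' protocols, total RNA was isolated with a column kit and 13 ng of it was labelled with a low-input amplification kit. How many animals were pooled for each sort, and which part of the intestine was used, is not given in the sources used here.

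Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 12.0.3.1. The submitters' processing notes name version 11.5.1.1 of the same software, and which version gave the values could not be settled. Per the file headers, the intensity of each spot was background-subtracted and detrended within the array by this software, with no scaling between arrays, and an error was given for it. The same deposited files hold flags of 0 or 1, also set by the software, for spots that were well above background, positive and significant, saturated, or outliers. The authors deposited in addition a table of processed intensity values. From the values themselves, each of its columns was the scanner's processed intensity multiplied by 1 constant per array, namely 10.9, 7.82, 11.9 and 9.08 for the Lgr5+ tuft marker+, Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker- arrays. These constants set the mean of each column to 2500 after trimming 2% of the spots at each end. The scale of that table was linear, it was not centred by gene, and its column medians were 279, 286, 365 and 253 in the same order. That this scaling was intended is an inference, since no label states it.

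Each array held 62976 spots, and all 4 lay on 1 slide read in 1 scan, so slide and scan did not separate the groups. Control spots were left out, as were 122, 96, 108 and 91 spots marked as outliers on the 4 arrays in the order above. No spot was saturated. The processed intensity was converted to log2, and the array's 75th percentile was subtracted, so that a level of 0 is the 75th percentile of that array. Copies of a probe were averaged. Among 300 probes spotted 10 times, the median standard deviation of the copies was 0.06 on each array on the log2 scale. Of 56605 probes, 32994 were named through the accession in the probe table and a RefSeq gene table of the GRCm38.p6 assembly, without versions on both sides, and gave 22911 genes. The other 23611 probes were not named and not used here. The array grid was annotated on the older mm9 build, so no coordinates are given.

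A gene was represented by its probe with the highest mean level over the 4 arrays, and was taken as above background where any of its probes was. The floor of an array was its lowest level among probes well above background, at -3.43, -3.87, -3.67 and -3.70 in the order above, and lower values were raised to it before differences were taken. A difference against a value raised to the floor, or against a gene not above background, is a lower limit and is given as "at least". A gene entered a pair of arrays if it was above background on at least 1 of them. Genes at least 2-fold apart were counted per pair, for both pairs of an axis in the same direction, and for 1 population against each of the other 3. Beside counts shared by both pairs stands the number that independent lists would share, taken from the genes past the threshold in each pair among those measured in both, so that these lists are smaller than the counts per pair. Errors are those the scanner software gave for each spot, carried through to the log2 difference, with a median of 0.21 in every pair. They cover the reading of the spots and not the variation between animals, sorts or labelling reactions. The median standard deviation between different probes of a gene was 0.44, 0.41, 0.39 and 0.31 in the 4 pairs (tuft marker within Lgr5+ and within Lgr5-, Lgr5 within tuft marker+ and within tuft marker-).

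There were no replicates, so nothing was tested between groups and no p-value is given. For each of 27 gene lists the median log2 difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile of the list's median among these describes the 4 arrays only. A list needed 4 or more measured members. Of 529 list members 515 had a probe. Of 107 combinations of list and pair, 54 lay outside the central 95% of the random lists, where 5.4 would for lists of genes drawn independently. Members of a list can vary together, some lists share members, and the 4 pairs use the same 4 arrays. The 5.4 is therefore not the number expected by chance for these lists. The lists held markers of tuft, Paneth, goblet, enterocyte, enteroendocrine and reserve stem cells, the Lgr5 stem cell signature and Wnt targets. Others held regenerative and fetal-like genes, eicosanoid synthesis, the IL-17RB and Notch pathways, and G2/M and S phase genes. For other cell types there were lists of T and NK cells, group 2 innate lymphoid and mast cells, B and plasma cells, myeloid, stromal, erythroid and epithelial cells. The remaining lists covered dissociation stress, the interferon response, glycolysis, oxidative phosphorylation, ribosomal proteins and the unfolded protein response. Further lists of 16 macrophage, 21 fibroblast and endothelial and 17 pancreatic acinar genes were written later and serve only the closing section.

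Genes were named by a fixed rule. It takes Lgr5, Il17rb, Epcam and Ctnnb1. For each axis it takes the 10 highest and 10 lowest genes that were above background on all 4 arrays and 2-fold apart the same way in both pairs, ranked by the smaller difference. It adds the 5 per direction above background on both bright arrays and neither dim one, ranked by the smaller limit. For Lgr5+ tuft marker+ cells it takes the 8 genes highest and 8 lowest against each other population, and the 5 at each end of the difference between both tuft marker differences. From each list it takes up to 4 members with the largest mean difference and the 1 farthest the other way. The 3264 genes with predicted or accession symbols were counted but not named, and a few genes that the rule takes are not reported here. The groups, comparisons, 27 lists, naming rule and the alternatives not marked as later were fixed before the data were examined.

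The alternatives were normexp background correction with an offset of 50 on spot medians followed by quantile normalization, quantile normalization alone, scaling to the median, the authors' scaled values, and the 75th percentile over probes above background on every array. Spot medians were used for normexp because spot means were not among the columns used here. Further alternatives were another detection flag, no detection filter with no floor, the mean of all probes of a gene, a 4-fold threshold, and the mean of a list in place of its median. After the data were seen, a difference beyond 2 scanner errors, genes with a mean level above 0 only, and leaving out the Lgr5- tuft marker+ array were added. An alternative without saturated spots was planned and not run, since there were none. The calculations were tested on simulated data with 200 of 22911 genes changed along the tuft marker axis. The changed genes were drawn from the 14053 above background on all 4 arrays, so recovery of dimmer genes was not tested. Every simulated array used the levels of the Lgr5- tuft marker- array and the real detection flags, and varied by the scanner error only. Variation between sorts and labelling reactions is therefore not in these numbers. At log2 changes of 1.5 and 3, 92% and 100.0% of the changed genes passed 2-fold in both pairs, and at -1.5 and -3, 98% and 100.0% did. Of 16557 unchanged genes, 33 passed in both pairs and 347 within Lgr5+. Of 400 combinations from 100 random lists of 20 genes, 4.0% lay outside the central range. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.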

Results

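Gene expression was compared between 4 populations of epithelial tumour cells from the mouse intestine, in which a stabilised form of beta-catenin was switched on in Lgr5-expressing cells 14 days before the cells were collected. Lgr5 is a receptor of intestinal stem cells, and tuft cells are rare chemosensory cells of the gut lining. The populations were Lgr5+ tuft marker+, Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker-, each on 1 array. There were no replicates, so the differences below describe these 4 arrays, and their number limits the precision. Of the spots, 60.2%, 68.9%, 69.0% and 64.3% were well above background in that order, which gave 15326, 16893, 17157 and 15949 genes. Levels are log2 signals relative to the 75th percentile of the array. Correlation between arrays over the 14053 genes above background on all 4 ran from a Pearson r of 0.905 between both Lgr5- arrays to 0.961 between both tuft marker- arrays. Genes are not independent replicates in these correlations.

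The genes behind the sort followed the labels. Il17rb, the receptor subunit for IL-25 used as the tuft marker, was 6.73-fold higher in tuft marker+ than in tuft marker- cells within Lgr5+ (log2 difference 2.75, error 0.29). Within Lgr5- it was at least 13.9-fold higher (at least 3.80), since it was not well above background in Lgr5- tuft marker- cells. After normexp these differences were 1.13 and 1.69, and with the mean of all probes that within Lgr5+ was 2.05. Lgr5 was 5.24-fold higher in Lgr5+ than in Lgr5- cells within tuft marker- (2.39, error 0.31) and at least 7.33-fold higher within tuft marker+ (at least 2.87). After normexp these were 0.87 and 1.16, and with a lower floor or none the latter was 5.05. Its level was the same to within the error in both Lgr5+ populations, at -0.80 with and -0.81 without the tuft marker. Epcam, the epithelial surface protein of the gate, stood at 5.01, 5.21, 4.50 and 5.55 in Lgr5+ tuft marker+, Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker- cells. Ctnnb1 stood at 5.06, 4.96, 4.37 and 5.22 in the same order.

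**Figure D1:**
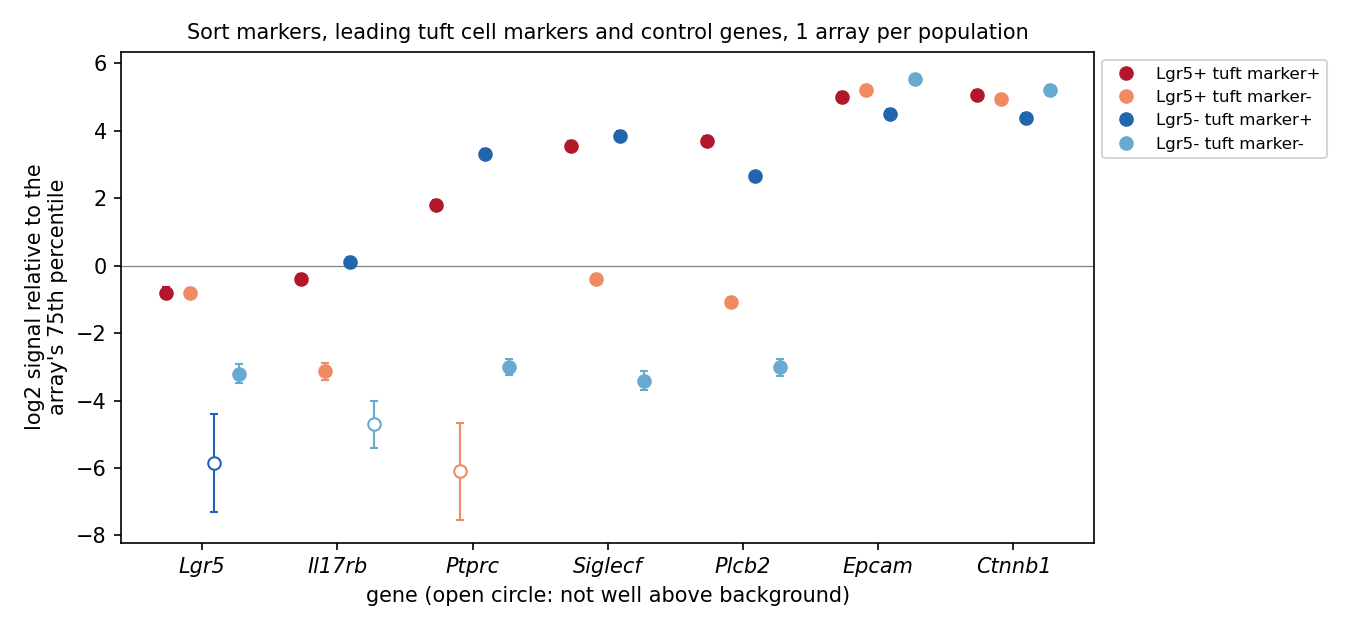
Log2 level relative to the array's 75th percentile (vertical axis) of the sort genes Lgr5 and Il17rb, 3 tuft cell genes, Epcam and Ctnnb1 on the 4 arrays, 1 point per array, with the scanner's error as bars and open circles where the gene was not well above background. Lgr5 lay at -0.80 and -0.81 on both Lgr5+ arrays, while Il17rb lay at -0.39 and 0.11 on both tuft marker+ arrays and at -3.14 on the Lgr5+ tuft marker- array.

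The comparison of tuft marker+ with tuft marker- cells asked what the tuft marker sort separated, within Lgr5+ and within Lgr5- cells. Tuft cell genes were higher in the tuft marker+ cells of both Lgr5 classes. The median difference of the tuft cell markers was 2.52 within Lgr5+ and 3.26 within Lgr5-, above all random lists in both. Of 42 measured members 34 were at least 2-fold higher within Lgr5+ and 36 of 42 within Lgr5-, with none 2-fold lower, and 33 of 41 were so in both pairs. Among the members with the largest differences, Siglecf, a sialic acid-binding lectin gene, was 15.4-fold and 153-fold higher. Plcb2, the phospholipase of taste signalling, followed at 27.2-fold and 50.7-fold. Ptprc, the gene for CD45, was at least 51.1-fold higher within Lgr5+ and 79.9-fold within Lgr5-. The kinase gene Dclk1 (3.48 and 3.93) and the tuft cell transcription factor gene Pou2f3 (1.44 and 2.65) were picked out after their values were seen. The taste receptor gene Tas1r3 was the member farthest the other way, at -0.48 and -0.08.

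Eicosanoid synthesis genes, which make prostaglandins and leukotrienes, were higher with the tuft marker in both classes, with medians of 0.90 (percentile 99.99) within Lgr5+ and 2.04 (100) within Lgr5-. Of 13 members measured in both pairs 7 were at least 2-fold higher in both. Among these, Ptgs1, Hpgds, Alox5, Alox5ap and Ltc4s are also in the tuft cell list, so this result in large part repeats that of the tuft cell markers. Alox5, the 5-lipoxygenase gene, differed by 3.73 within Lgr5+ and at least 4.62 within Lgr5-, and Ptgs2, the inducible cyclooxygenase gene, by 3.68 and 3.31. Ptgs1 differed by at least 2.79 and at least 3.48. Such genes are also expressed by macrophages and mast cells, and the myeloid markers below moved with them (medians 1.28 and 1.60), so the cell that gave this signal is not known from these values. The IL-17RB pathway list lay inside the random range, with medians of 0.24 (81.3) within Lgr5+ and 0.09 (54.1) within Lgr5-, where scaling to the median turned the sign to -0.14. Interferon response genes were higher in both classes, with medians of 1.15 (100) and 0.91 (99.9), and 6 of 19 members were at least 2-fold higher in both pairs. Among them Gbp2 was 9.23-fold and 8.60-fold higher and Rsad2 9.74-fold and 4.43-fold. Notch pathway genes had medians of 0.50 (98.2) and 0.24 (81.3), with the receptor gene Notch2 at 1.94 and 1.54. Within Lgr5+ the list fell inside the random range after normexp (97.2) and with the mean of the list (92.1). Regenerative and fetal-like genes had medians of 0.36 (96.2) and 0.50 (95.6), with Il1rn at 3.60 and 3.58 and Spp1 at least 5.39 and at least 5.60 higher, and both are macrophage genes as well.

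Beside these groups, markers of other cell types were also higher in tuft marker+ cells. Myeloid markers had medians of 1.28 within Lgr5+ and 1.60 within Lgr5-, above all random lists in both, and 10 of 18 members were at least 2-fold higher in both pairs. The complement gene C1qc differed by at least 6.64 and 5.92, the macrophage gene Adgre1 by at least 5.43 and 5.10, and the adaptor gene Tyrobp by 5.62 and 4.28. Lyz2, a lysozyme gene that may share probe sequence with Lyz1, stood apart at -0.61 and 0.34. The list also holds Itgam (0.35 and 0.15), Csf1r (-0.05 and 0.15) and Siglech (0.44 and 0.43), picked out after their values were seen, whose probes were bright and nearly flat on all arrays and may read other transcripts. Stromal markers had medians of 1.32 and 1.96, above all random lists in both, with the intermediate filament gene Vim at 4.68 and 5.08 and the collagen gene Col3a1 at 3.19 and 4.94. Dcn, a matrix proteoglycan gene, differed by 2.76 and at least 5.24. Markers of group 2 innate lymphoid and mast cells had medians of 0.60 (98.9) and 1.15 (99.8), with Il7r at 1.71 and 3.44 and Rora at 1.90 and 3.11. Within Lgr5+ that list fell inside the random range with no detection filter (97.3) and with the mean of the list (94.7). T and NK cell markers had medians of -0.28 (9.09) within Lgr5+ and 0.99 (99.96) within Lgr5-, and B and plasma cell markers of 0.30 (83.6) and 1.11 (98.98). The latter fell inside the random range with the other detection flag (93.8) and with no filter (91.2). Of erythroid markers 3 were measured within Lgr5+, too few for a percentile, and the median within Lgr5- was 0.23 (43.8).

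Genes of the other secretory lineages were lower in tuft marker+ cells, but within Lgr5- so were epithelial markers at large (-0.99), by more than the Paneth and enteroendocrine markers, while myeloid (1.60) and stromal markers (1.96) were higher. Goblet cell markers had medians of -0.65 within Lgr5+ and -1.44 within Lgr5-, below all random lists in both, and 5 of 17 members were at least 2-fold lower in both pairs. Retnlb, a goblet cell resistin-like gene, was 3.60-fold and 4.45-fold lower, Zg16 was 4.30-fold and 2.95-fold lower, and Clca1 was 4.83-fold and 2.51-fold lower, while the chemokine gene Ccl6 differed by 0.85 and 1.60. Enteroendocrine markers had medians of -0.55 (0.29) and -0.80 (0.03), with chromogranin A (Chga) at -1.05 and -2.94 and ghrelin (Ghrl) at -2.56 and -1.17. Paneth cell markers had medians of -0.37 (0.23) and -0.80 (0.66), with the metalloproteinase gene Mmp7 at -1.18 and -1.53. Enterocyte markers were higher with the tuft marker within Lgr5+, at 0.85 (100), where Apoc3 differed by 4.01 and Apoa4 by 3.12. Within Lgr5- their median was -0.27 (29.1), which the authors' scaled values turned to 0.03.

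The Lgr5 stem cell signature and G2/M phase genes were lower in tuft marker+ cells of both classes. The signature had medians of -0.26 (1.96) within Lgr5+, which lay inside the random range when the mean of the list was used (3.97), and -0.69 (0.15) within Lgr5-. Of its 29 members measured in both pairs 1 was at least 2-fold lower in both, and that was Ascl2, a stem cell transcription factor gene, at -1.16 and -1.03. G2/M phase genes had medians of -0.33 (1.95) and -1.11 (below all random lists), with the mitotic kinesin gene Kif11 4.43-fold and 4.83-fold lower and Ccnb1 at -1.29 and -2.17. S phase genes had a median of -0.71 (0.31) within Lgr5- and of 0.00 (41.1) within Lgr5+, where the sign followed the scaling, at 0.10 when scaled to the median and -0.02 after normexp. Wnt targets lay inside the random range at -0.15 (16.8) and -0.26 (14.9), the latter turned to 0.04 by the authors' scaled values. They lay below the range within Lgr5+ after normexp (2.07) and within Lgr5- with the mean of all probes of a gene (2.10). Reserve stem cell markers lay inside the random range at -0.38 (19.9) and -0.73 (6.86). Within Lgr5- the epithelial markers (-0.99), ribosomal protein genes (-0.93) and oxidative phosphorylation genes (-1.01) were lower by more than the signature and S phase genes, and about as much as G2/M phase genes, while stromal (1.96) and myeloid markers (1.60) were higher.

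Metabolic and housekeeping lists were set beside these. Within Lgr5-, tuft marker+ cells had lower levels of genes for oxidative phosphorylation (-1.01) and ribosomal proteins (-0.93), both below all random lists, and of glycolysis (-0.79, percentile 0.49). Within Lgr5+ these lists had medians of 0.15 (67.8), -0.21 (0.07) and 0.54 (99.85), so ribosomal protein genes were below the random range in both classes. The ribosomal protein gene Rps14 differed by -1.54 and -1.65 within Lgr5+ and Lgr5-, and the hexokinase gene Hk1 by 3.60 and 1.83. The unfolded protein response had medians of 0.17 (72.0) and -0.37 (25.4). Epithelial markers had a median of -0.99 (0.03) within Lgr5-, with the keratin gene Krt19 at -1.88 and Krt18 at 1.58. Within Lgr5+ the epithelial median was -0.08 (17.6), which scaling to the median turned to 0.02. Dissociation stress genes had medians of 0.13 (61.5) within Lgr5+ and 0.05 (60.5) within Lgr5-, the latter turned to -0.18 by scaling to the median.

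Gene by gene on this axis, the highest of those above background on all 4 arrays was Mmp12, a macrophage metalloelastase, at 237-fold within Lgr5+ and 174-fold within Lgr5-. Apoe, an apolipoprotein gene, was 114-fold and 30.4-fold higher and Sirpa, a myeloid receptor gene, 98.4-fold and 35.2-fold. Gprc5c was at least 111-fold and at least 65.5-fold higher, and Rgs1, a regulator of G protein signalling, 67.5-fold and 47.7-fold. The others of the leading 10 were Pla2g7, Cybb, Msn, Ly6g6d and Plcb2. Genes above background on both tuft marker+ arrays and on neither other array were led by Spp1, at least 42.1-fold and at least 48.6-fold higher, and F13a1, at least 35.4-fold and at least 40.4-fold higher, followed by Gpnmb, Arhgap45 and Ly86. The lowest genes included Kif11, Retnlb, the diphthamide gene Dph6, at 4.69-fold and 4.39-fold lower, and the splicing factor gene Prpf4, at 4.38-fold and 4.61-fold lower. The others of that set were Ftsj1, Atp8b1, Gcnt4, Impa2, H4f16 and Rrp36. Among genes above background on both tuft marker- arrays alone, the cell cycle phosphatase gene Cdc25c was at least 4.25-fold and at least 7.44-fold lower.

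Within Lgr5+, 1806 genes were at least 2-fold higher and 1433 lower of 17501 measured, a share of 55.8% higher that became 76.7% (619 and 188) after normexp. Within Lgr5-, 2922 were higher and 2192 lower of 17911, a share of 57.1% that became 37.0% (2005 and 3421) when scaled to the median and 79.5% (4426 and 1144) with the authors' scaled values. In both pairs 796 genes were higher and 234 lower, where independent lists would share 278.2 and 175.3, and 450 went opposite ways, of 16757 genes. After normexp the shared counts were 361 and 23. The pairs share no array. Across the 14053 genes above background on all 4 arrays, both tuft marker differences had a Pearson r of 0.22 and a Spearman rho of -0.0042. The median difference of these genes, 0.02 within Lgr5+ and -0.04 within Lgr5-, became 0.12 and -0.27 when scaled to the median and 0.08 and 0.26 with the authors' scaled values. Within Lgr5- it became 0.08 when the 75th percentile was taken over probes above background on every array.

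**Figure D2:**
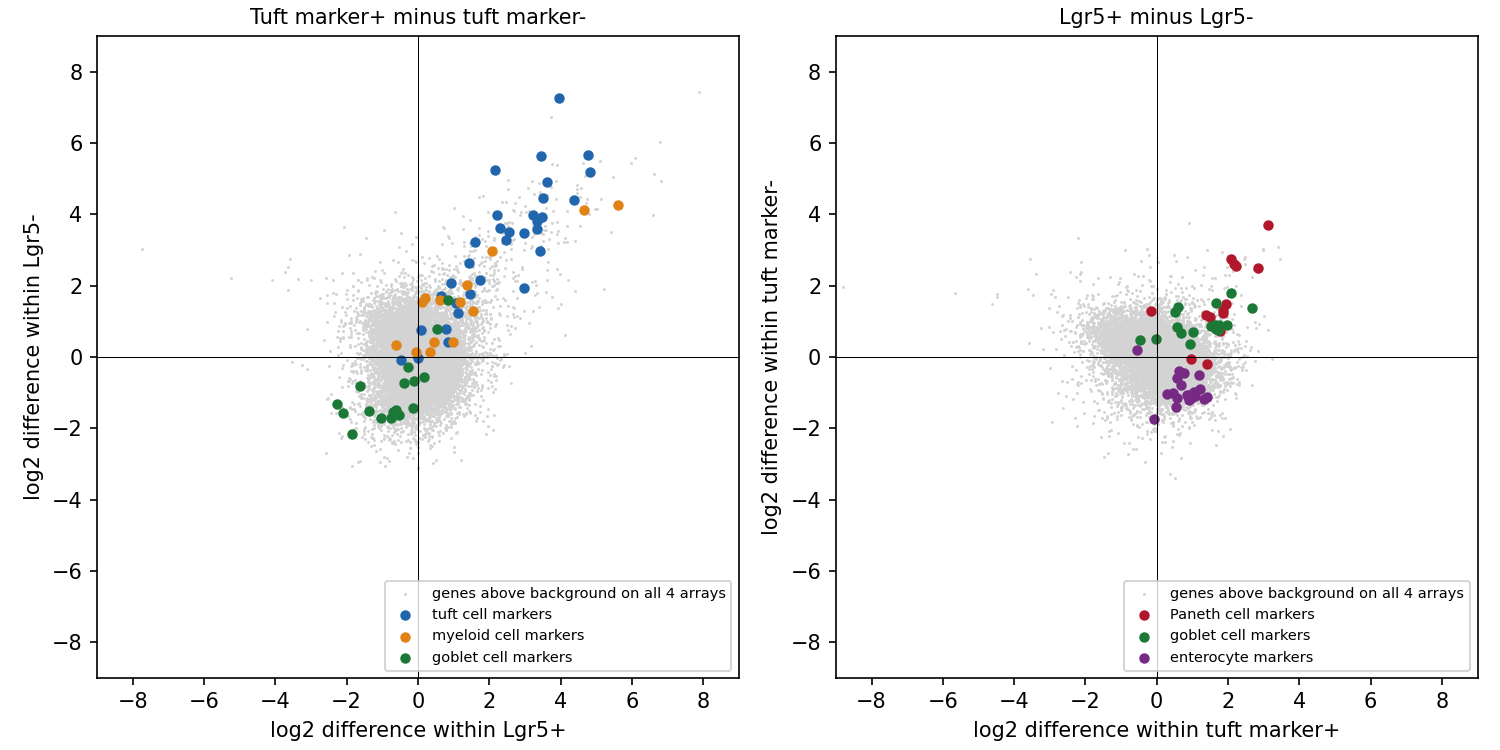
Each point is a gene, with log2 differences of tuft marker+ minus tuft marker- cells within Lgr5+ (horizontal) and Lgr5- (vertical) on the left, and of Lgr5+ minus Lgr5- cells within tuft marker+ (horizontal) and tuft marker- (vertical) on the right, for the 14053 genes above background on all 4 arrays. Tuft cell markers had medians of 2.52 and 3.26 on the left, and on the right Paneth cell markers had medians of 1.86 and 1.31 while enterocyte markers had medians of 0.76 and -1.02.

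The comparison of Lgr5+ with Lgr5- cells asked what the stem cell receptor separated, within tuft marker+ and within tuft marker- cells. Paneth cell genes were higher in Lgr5+ cells of both classes. The median of the Paneth cell markers was 1.86 within tuft marker+ and 1.31 within tuft marker-, above all random lists in both, and 10 of 14 members were at least 2-fold higher in both pairs. The defensin gene Defa21 was 8.74-fold and 13.1-fold higher and Habp2, a hyaluronan-binding protease gene, 4.69-fold and 5.92-fold. Defensin genes are near-identical copies, so their probes may read each other's transcripts and each value is uncertain. Goblet cell markers were also higher in Lgr5+ cells, with medians of 1.53 and 0.88, above all random lists in both. All 3 members at least 2-fold higher in both pairs were among those named by rule, namely Ern2, a goblet cell stress sensor gene, at 2.68 and 1.38, Retnlb at 2.09 and 1.79, and Spink4 at 1.65 and 1.51.

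The Lgr5 stem cell signature was higher in Lgr5+ cells, with medians of 0.71 (100) within tuft marker+ and 0.37 (99.86) within tuft marker-. It holds Lgr5 itself. Within tuft marker+ the epithelial markers (0.70) and ribosomal protein genes (0.60) were higher by about as much and stromal markers were lower (-1.06), so the signature did not stand out from epithelial genes at large there. At least 2-fold higher were 10 of 29 members within tuft marker+ and 2 of 30 within tuft marker-, while 3 and 2 were at least 2-fold lower. Besides Lgr5, the matrix gene Smoc2 was 3.16-fold and 2.97-fold higher, and the receptor gene Lrig1 differed by 1.99 and 0.84. Ascl2 went the other way, at -0.69 and -0.57, and Igfbp4 at -0.46 and -1.68. Reserve stem cell markers, which include Lrig1, had medians of 1.36 (99.91) and 0.32 (81.7), with Hopx at 1.36 and 0.09, and after normexp the former lay inside the random range (94.5). Wnt targets lay inside the random range at 0.04 (59.5), which the authors' scaled values turned to -0.12, and at 0.22 (93.8). These targets lay above the range within tuft marker+ with the mean of the list (97.7). Within tuft marker- they did so after normexp (99.9) and after quantile normalization (97.7). Among them Nkd1, an inhibitor induced by Wnt, was higher by at least 2.05 and at least 1.16.

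Enterocyte, energy metabolism and epithelial lists differed in direction between the tuft marker classes, a difference that was not tested. Enterocyte markers had a median of 0.76 (99.97) within tuft marker+ and of -1.02, below all random lists, within tuft marker-. Within tuft marker- 12 of 21 members were at least 2-fold lower in Lgr5+ cells, with the fatty acid-binding protein genes Fabp1 at -1.74 and Fabp2 at -1.39, against -0.07 and 0.55 within tuft marker+. Oxidative phosphorylation genes had medians of 0.59 (99.6) and -0.40 (0.51), glycolysis genes 0.37 (88.3) and -0.91 (below all random lists), and epithelial markers 0.70 (99.7) and -0.33 (4.48). Ribosomal protein genes had medians of 0.60 (99.98) and -0.16 (26.8). The unfolded protein response stood at 0.54 (95.4) within tuft marker+ and at -0.04 (65.4) within tuft marker-, where the sign turned to 0.05 after normexp.

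Between both tuft marker+ populations the median of the tuft cell markers was -0.04 (27.4), which scaling to the median turned to 0.18. It was -0.18 after normexp (percentile 0.56) and -0.25 after quantile normalization (1.06), both below the random range. Between the tuft marker- populations they were higher in Lgr5+ cells, with a median of 0.67 (100) and 12 of 39 members at least 2-fold higher. There Siglecf was 8.18-fold higher and Trpm5, the tuft cell cation channel gene, 6.53-fold. Eicosanoid synthesis genes had medians of -0.26 (18.9) within tuft marker+ and 0.12 (73.6) within tuft marker-. G2/M phase genes had medians of 0.30 (89.2) and -0.31 (2.0), the latter inside the random range after quantile normalization (3.08), and S phase genes of 0.09 (48.0), which the authors' scaled values turned to -0.08, and -0.36 (1.18). Enteroendocrine markers stood at -0.06 (52.7), turned to 0.16 by scaling to the median, and at -0.21 (8.77), with Cck at -2.19 as a limit and -1.65. Dissociation stress genes had medians of 0.29 (80.1) and 0.27 (99.2), the latter inside the random range with the mean of the list (93.6), and regenerative and fetal-like genes of -0.30 (10.3) and -0.19 (19.9).

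Markers of other cell types were lower in the Lgr5+ than in the Lgr5- tuft marker+ cells. Stromal markers had a median of -1.06 and T and NK cell markers of -1.02 there, both below all random lists, and myeloid markers of -0.64 (0.02). The granzyme gene Gzma was 7.70-fold lower within tuft marker+ and 3.52-fold lower within tuft marker-, and Col3a1 was 6.77-fold and 2.02-fold lower. Within tuft marker-, myeloid markers had a median of -0.33 (3.72). The stromal median there was -0.02 (51.1) and turned to 0.05 with the authors' scaled values, and the T and NK cell median was 0.07 (66.8) and turned to -0.04 when scaled to the median. Group 2 innate lymphoid and mast cell markers had a median of -0.37 (22.8) within tuft marker+, with Kit, a receptor kinase gene, at 2.75 and Rora at -2.63. B and plasma cell markers had a median of -0.56 (8.94), erythroid markers of -0.27 (35.1) and interferon response genes of -0.26 (13.7) within tuft marker+. Within tuft marker- the interferon median was -0.34 (2.58).

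Gene by gene, the 10 highest in Lgr5+ cells were Defa21, Defa2, Mptx1, Ang2, Mptx2, Defa26, Defa38, Defa43, Defa42 and Defa36. Defa2 was 10.5-fold and 8.44-fold higher, the pentraxin genes Mptx1 7.97-fold and 7.96-fold and Mptx2 10.9-fold and 6.71-fold, and the angiogenin gene Ang2 7.93-fold and 8.22-fold. Genes above background on both Lgr5+ arrays alone were led by the methyltransferase gene Prdm8, at least 5.03-fold and at least 4.78-fold higher, and Dact2, an inhibitor of Wnt signalling, at least 5.31-fold and at least 4.01-fold. They also held Bhlha15, the secretory cell transcription factor MIST1, at least 3.72-fold and at least 3.91-fold higher. The lowest were the alkaline phosphatase gene Alpl, 4.75-fold and 3.83-fold lower, Gzma, and Prpf4, at 3.42-fold and 3.60-fold lower. With them stood the lectin-like receptor gene Klra2, 4.90-fold and 3.28-fold lower. Igfbp7 and Zeb2, both high in stromal or myeloid cells, were also among the lowest 10, at -1.64 and -1.49 and at -1.48 and -1.55.

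Within tuft marker+, 1562 genes were at least 2-fold higher and 2008 lower in Lgr5+ cells of 17625 measured, a share of 43.8% higher that became 66.9% (2589 and 1281) when scaled to the median and 28% (1060 and 2728) with the authors' scaled values. Within tuft marker-, 1129 were higher and 919 lower of 17527, a share of 55.1% that became 41.3% (868 and 1236) when scaled to the median. In both pairs 119 genes were higher and 96 lower, where independent lists would share 94.3 and 91.8, and 408 went opposite ways, of 16497 genes. After normexp the shared counts were 34 and 11. Across the 14053 genes, both Lgr5 differences had a Pearson r of -0.28 and a Spearman rho of -0.36. Their median difference, 0.05 within tuft marker+ and -0.04 within tuft marker-, became 0.28 and -0.15 when scaled to the median and -0.11 and 0.03 with the authors' scaled values.

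**Figure D3:**
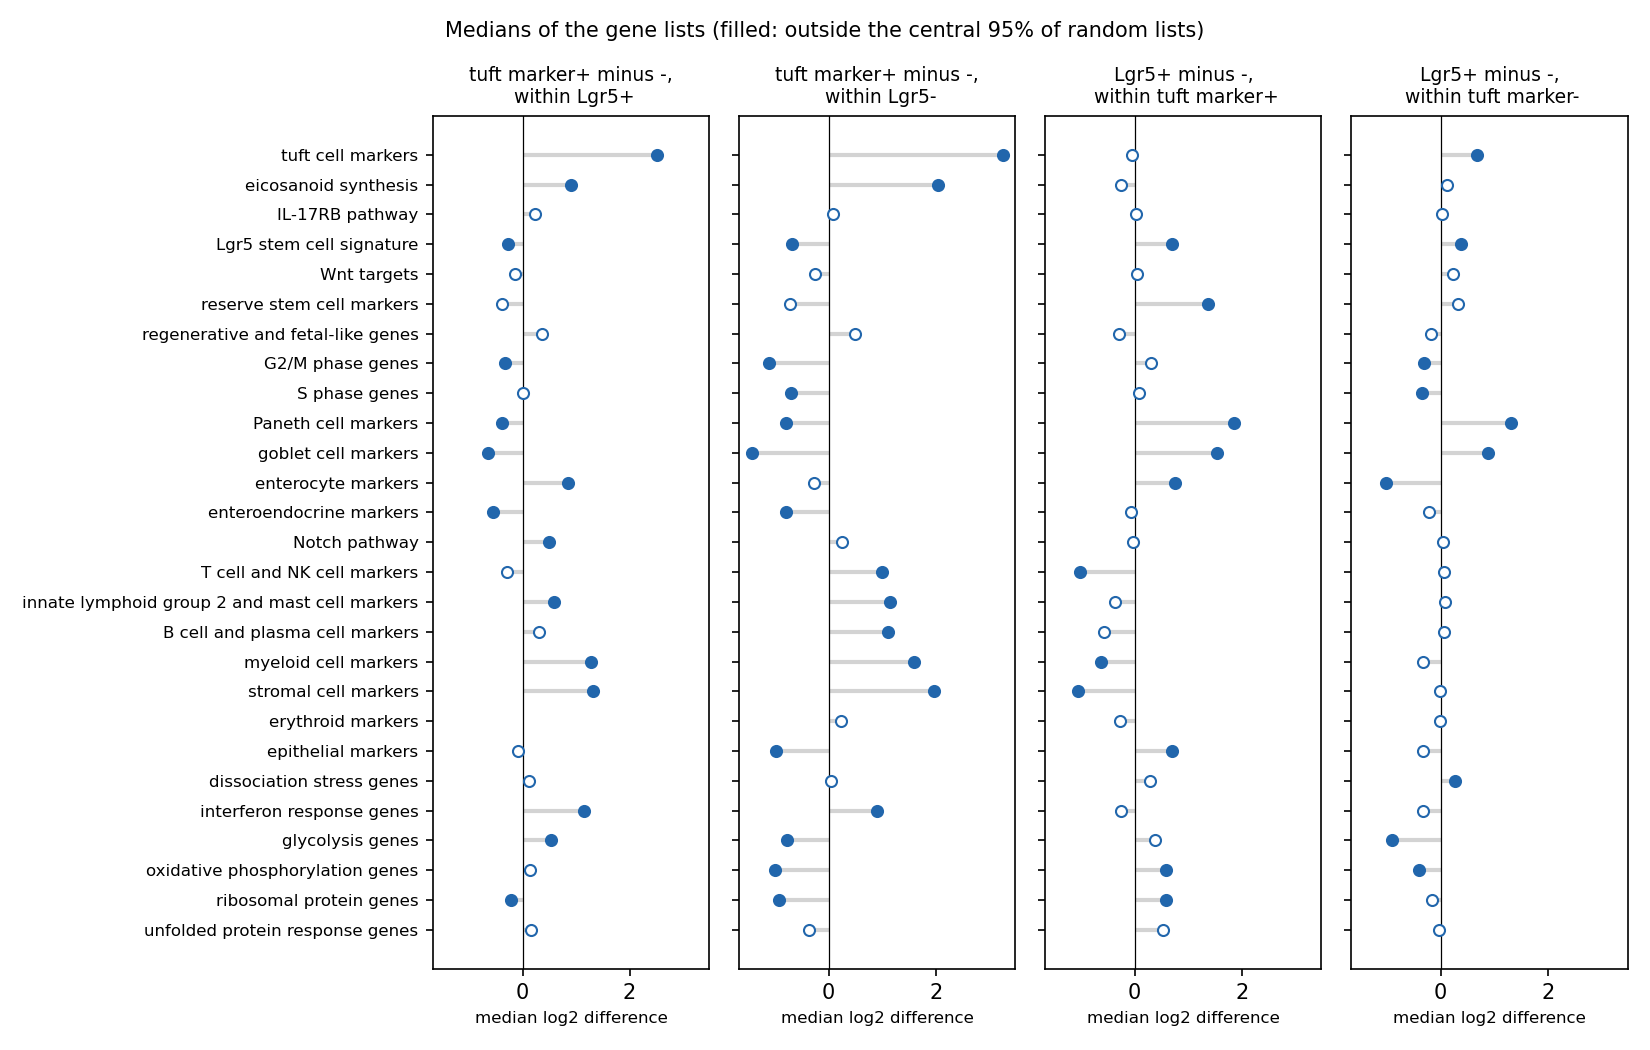
Median log2 difference (horizontal axis) of 27 gene lists (vertical axis) in the 4 pairs of arrays, filled where the median lay outside the central 95% of 10000 random lists. The 4 panels show the tuft cell markers at 2.52, 3.26, -0.04 (0.18 when scaled to the median) and 0.67, and the goblet cell markers at -0.65, -1.44, 1.53 and 0.88.

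The series title names the Lgr5+ tuft marker+ cells, so each population was also set against the other 3. In Lgr5+ tuft marker+ cells the gene with the largest margin upwards was Cfd, the complement factor D gene, with a level of 1.58 against -3.63, -1.65 and -3.56 in Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker- cells. It was 37.1-fold higher than in Lgr5+ tuft marker- and 9.39-fold higher than in Lgr5- tuft marker+ cells. Mme, the gene for the peptidase neprilysin, was 7.97-fold and 6.75-fold higher and the cytokine gene Il15 5.30-fold and 5.11-fold. The others highest there were Ampd3, Epha7, Prph, Aldh6a1 and Dusp28. Pancreatic enzyme genes were lowest in these cells, with the amylase gene Amy2a5 at -2.73 against 5.01, 6.07 and 3.04, and Try5, Ctrb1, Cpa1 and Amy1 in the same set. Amylase and trypsinogen genes are near-identical copies and are uncertain one by one. Outside that group, the tensin gene Tns3 was 9.51-fold lower than in Lgr5+ tuft marker- and 7.06-fold lower than in Lgr5- tuft marker+ cells. The growth factor receptor gene Fgfr3 was 8.60-fold and 4.44-fold lower and the cell surface receptor gene Cdon 4.29-fold and 4.80-fold lower.

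In Lgr5+ tuft marker+ cells 263 genes were at least 2-fold higher and 157 lower than in each of the other 3, of 18655 genes measured, with splits of 39 and 13 after normexp and 340 and 115 when scaled to the median. The counts were 190 and 197 in Lgr5+ tuft marker-, 680 and 442 in Lgr5- tuft marker+, and 228 and 193 in Lgr5- tuft marker- cells. For Lgr5- tuft marker+ cells the split was 211 and 64 after normexp, 420 and 754 when scaled to the median, and 1098 and 219 with the authors' scaled values. For Lgr5- tuft marker- cells it was 285 and 144 when scaled to the median and 143 and 273 with the authors' scaled values. Without the Lgr5- tuft marker+ array, a choice made after the data were seen, both remaining populations were tuft marker-. Then 1072 genes were higher and 396 lower in Lgr5+ tuft marker+ cells than in each of them.

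The tuft marker difference itself differed by at least 2-fold between the Lgr5 classes and was larger within Lgr5+ for 3127 genes and smaller for 3535. That split became 4919 and 2342 when scaled to the median and 2137 and 4542 with the authors' scaled values. The largest excess within Lgr5+ was that of Slc2a5, the fructose transporter gene, which differed by 2.09 within Lgr5+ and -2.05 within Lgr5-. Cmss1, Acrbp, Napg and Entpd7 came next. At the other end stood the pancreatic enzyme genes, with Amy2a5 at -7.74 and 3.03. With 1 array per population this difference of differences has no residual degrees of freedom.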

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

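Among the tests below, only the one on macrophage genes expressed by tuft cells in a fixed ratio was chosen after its result was seen.

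Macrophage and stromal genes were far higher in the tuft marker+ sorts, although the EpCAM+ gate would remove the cells that make them. A hypothesis is RNA or cells of other types in those sorts. A separate set of 16 macrophage genes, none (0) of them in the tuft cell list, had medians of 3.55 within Lgr5+ and 3.87 within Lgr5- (the lower percentile of both 100). Fibroblast and endothelial genes had 0.75 and 1.49 (lower percentile 99.75), so both medians would fit that source. The stromal set was less uniform within Lgr5+. There 4 of its 13 measured genes were at least 2-fold higher and 1, the endothelial gene Plvap (-1.19), was lower, against 13 of 15 macrophage genes higher. Within Lgr5- 14 of 20 and 16 of 16 were at least 2-fold higher. Among abundant macrophage genes, levels in Lgr5+ tuft marker+, Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker- cells were 6.90, 3.01, 7.48 and 3.70 for Ctss and 7.53, 0.70, 8.34 and 3.42 for Apoe, but 2.33, 2.12, 3.28 and 1.64 for C1qb and 1.99, 2.60, 1.59 and 1.25 for Lyz2, which macrophage RNA alone would not give unless those probes read other transcripts. The other hypothesis, that tuft cells make these genes in a fixed ratio to their markers, was argued against, since between both tuft marker+ arrays the stromal set differed by -1.26 and the macrophage set by -1.17, where the quartiles of the tuft cell markers were -0.30 and 0.24. Expression by tuft cells that differs with Lgr5 remains untested.

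Pancreatic enzyme genes were lowest in Lgr5+ tuft marker+ cells. A hypothesis is RNA of pancreatic acinar cells carried into the other 3 sorts, and of 16 measured genes in a separate acinar set 81.2% (13) were lowest on the Lgr5+ tuft marker+ array, which fits it. That the array with the highest Amy2a5, Lgr5- tuft marker+, carried the most acinar RNA could not be told apart from other sources, since 56.2% (9 of 16) of the set were highest there. Prss2 stood at -5.49 (not above background), 2.71, 2.79 and -0.50 in the order above, whereas the acinar gene Clps stood at 3.42, 4.61, 3.53 and 2.63. Expression of these genes by tumour cells was not tested.

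Tuft cell markers were higher in Lgr5+ than in Lgr5- tuft marker- cells, with a median of 0.67. A hypothesis is a fixed share of tuft marker+ cells left in the Lgr5+ tuft marker- sort, which would give every marker the same share of its level in Lgr5+ tuft marker+ cells. The share was taken over 29 markers above background in both Lgr5+ populations. Each was at least 2-fold higher in Lgr5+ tuft marker+ than in Lgr5+ tuft marker- cells. That choice leaves out markers with a large share, so the median share is low partly by construction. It was 4.35% (quartiles 2.04 and 8.87), with 25 markers above 0, and 58.6% (17) lay within 3-fold of it. Such a share and weak expression of tuft cell genes by the Lgr5+ tuft marker- cells themselves cannot be told apart here.

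For the genes and lists that follow the pairs of an axis differed in direction, and the difference was not tested. Tuft marker differences within Lgr5+ and within Lgr5- were -7.74 and 3.03 for Amy2a5, -5.25 and 2.21 for Try5, -4.11 and 2.15 for Ctrb1, -3.73 and 2.37 for Cpa1, and -3.63 and 2.53 for Amy1. They were 2.09 and -2.05 for Slc2a5, 1.20 and -2.88 for Cmss1, 1.91 and -2.16 for Acrbp, 1.98 and -1.92 for Napg, 2.14 and -1.64 for Entpd7, and 0.54 and -0.79 for the glycolysis genes. Lgr5 differences within tuft marker+ and within tuft marker- were -8.80 and 1.97 for Amy2a5, -5.67 and 1.79 for Try5, -4.49 and 1.76 for Ctrb1, -4.61 and 1.49 for Cpa1, and -4.49 and 1.67 for Amy1. They were 1.67 and -2.47 for Slc2a5, 1.86 and -2.23 for Cmss1, 2.06 and -2.01 for Acrbp, and 1.72 and -2.07 for Entpd7. Enterocyte markers stood at 0.76 and -1.02, and oxidative phosphorylation genes at 0.59 and -0.40.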

How the results depend on the processing

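A difference beyond 2 scanner errors, genes with a mean level above 0 only, and leaving out the Lgr5- tuft marker+ array were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each population had 1 array and the results come from no test. Signal over background compares a population's share of RNA and not its amount per cell, so a higher share of some genes lowers the others. An alternative without saturated spots was not run, since no spot was saturated. Of 963 list percentiles recalculated 930 kept their call, 23 became stronger and 10 weaker. The 963 include scaling to the median, the authors' scaled values and the percentile scaling over probes above background on every array. Each of those scalings moves all genes of an array by a constant. A list and its random lists then shift equally, so these percentiles could not change and say nothing about stability. Of 246 counts 135 stayed within 1.5-fold of the main value and 111 did not. Of 4200 recalculated differences of named genes that were at least 2-fold in the main values 3188 stayed within the scanner error of the main difference, 1008 moved farther and 4 changed sign, and of 32 sort gene differences 23 stayed within that error and 9 moved farther. Of 16 correlations 14 stayed within 0.05 of the main value and 2 did not. The scalings by a constant could not move a correlation either. Requiring differences beyond 2 scanner errors was applied only to the counts per pair and for both pairs of an axis. It moved none of those counts beyond 1.5-fold.

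With a 4-fold threshold counts fell because it is stricter. Within Lgr5+ 509 genes were higher and 148 lower with the tuft marker (main 1806 and 1433), within Lgr5- 754 and 184 (2922 and 2192), and in both 322 and 12 (796 and 234), with 26 opposite (450). For Lgr5 there were 158 and 247 within tuft marker+ (1562 and 2008), 137 and 99 within tuft marker- (1129 and 919), and 20 and 5 in both (119 and 96), with 18 opposite (408). Against each other population there were 28 and 19 in Lgr5+ tuft marker+ (263 and 157), 16 and 24 in Lgr5+ tuft marker- (190 and 197), 80 and 16 in Lgr5- tuft marker+ (680 and 442), and 15 and 10 in Lgr5- tuft marker- cells (228 and 193). The tuft marker difference was larger in Lgr5+ for 462 and smaller for 897 (3127 and 3535).

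Genes with a mean level above 0 are fewer by construction. Of these 460 and 275 were higher and lower with the tuft marker within Lgr5+, 684 and 915 within Lgr5-, and 195 and 54 in both, with 59 opposite. For Lgr5 there were 542 and 352 within tuft marker+, 140 and 205 within tuft marker-, and 32 and 19 in both, with 44 opposite. Without the Lgr5- tuft marker+ array 1072 genes were higher and 396 lower in Lgr5+ tuft marker+ cells than in each remaining population (263 and 157). Fewer arrays had to be passed, and both remaining populations were tuft marker-. Genes that both tuft marker+ populations share could therefore count as well. No other array was left out for comparison.

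With detection by positive and significant signal, and likewise with no filter and no floor, dimmer genes entered and counts grew. Both gave 2841 lower within Lgr5+ (1433), 4385 higher within Lgr5- (2922), 433 lower in both (234) and 1048 opposite (450). For Lgr5 both gave 3756 lower within tuft marker+ (2008), 2327 and 1708 within tuft marker- (1129 and 919), and 214 and 358 in both (119 and 96), with 1041 opposite (408). Against each other population both gave 642 lower in Lgr5+ tuft marker+ (157), 400 higher in Lgr5+ tuft marker- (190), 1149 higher in Lgr5- tuft marker+ (680), and 382 and 573 in Lgr5- tuft marker- cells (228 and 193). Lower in Lgr5+ tuft marker- were 453 with the flag and 454 without a filter (197), and smaller tuft marker differences in Lgr5+ were 5481 and 5670 (3535). Both raised the Lgr5 difference within tuft marker+ to 5.05 (2.87) and the Il17rb difference within Lgr5- to 4.81 (3.80), since the floor was lower or absent. The correlation of the Lgr5 differences was -0.209 with the flag and -0.188 without a filter (-0.278).

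In the same order, percentiles were 93.8 and 91.2 for B and plasma cell markers by tuft marker within Lgr5- (98.98). By Lgr5 they were 1.62 and 1.53 for erythroid markers within tuft marker+ (35.1) and 0.83 and 0.61 within tuft marker- (36.3), 0.68 and 0.73 for myeloid markers within tuft marker- (3.72), and 0.81 and 0.87 for regenerative genes there (19.9). Without a filter that of group 2 innate lymphoid and mast cell markers within Lgr5+ was 97.3 (98.9). The cause was not tested.

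After normexp differences were smaller. Input, background correction, offset and normalization all differed from the main values. Quantile normalization alone, on the main intensities, did not shrink the counts in this way. By tuft marker it gave 1951 and 1186 genes within Lgr5+ and 2639 and 2400 within Lgr5-. Which of the input, background correction and offset made the differences smaller was not tested. Il17rb differed by 1.13 and 1.69 within Lgr5+ and Lgr5- (2.75 and 3.80), and Lgr5 by 1.16 and 0.87 within tuft marker+ and tuft marker- (2.87 and 2.39). By tuft marker there were 619 and 188 genes within Lgr5+, 1170 and 587 within Lgr5-, and 361 and 23 in both, with 44 opposite. By Lgr5 there were 391 and 560 within tuft marker+, 126 and 125 within tuft marker-, and 34 and 11 in both, with 30 opposite. Against each other population there were 39 and 13 in Lgr5+ tuft marker+, 18 and 19 in Lgr5+ tuft marker-, 211 and 64 in Lgr5- tuft marker+, and 24 and 15 in Lgr5- tuft marker- cells. The tuft marker difference was larger in Lgr5+ for 1194 and smaller for 1421. The main values of these counts stand with the 4-fold threshold above.

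Percentiles after normexp were 2.07 for Wnt targets (16.8) and 97.2 for the Notch pathway (98.2) by tuft marker within Lgr5+. By Lgr5 within tuft marker+ they were 0.56 for tuft cell markers (27.4) and 94.5 for reserve stem cell markers (99.91). Within tuft marker- they were 99.9 for Wnt targets (93.8), 2.01 for epithelial markers (4.48) and 1.84 for interferon genes (2.58). Quantile normalization alone gave 1.06 for tuft cell markers within tuft marker+, and 97.7 for Wnt targets and 3.08 for G2/M phase genes (2.0) within tuft marker-. The cause was not tested.

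Scaling to the median gave 3421 lower by tuft marker within Lgr5- (2192), 2589 and 1281 by Lgr5 within tuft marker+ (1562 and 2008), 420 and 754 in Lgr5- tuft marker+ cells against each other population (680 and 442), and 4919 larger and 2342 smaller tuft marker differences in Lgr5+ (3127 and 3535). The authors' scaled values gave 4426 and 1144 by tuft marker within Lgr5- (2922 and 2192), 149 lower in both (234), 1098 and 219 in Lgr5- tuft marker+ (680 and 442), and 143 higher in Lgr5- tuft marker- cells (228). Both move all genes of an array by a constant.

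With the mean of all probes 4 differences changed sign, namely Aurkb within Lgr5- at -0.46 (1.67), Klrg1 at 0.44 within Lgr5+ (-1.13) and -0.76 within Lgr5- (1.22), and Plcb2 by Lgr5 within tuft marker- at -0.17 (1.95). Il17rb within Lgr5+ was 2.05 (2.75). Percentiles were 2.10 for Wnt targets within Lgr5- (14.9) and 0.26 for B and plasma cell markers by Lgr5 within tuft marker+ (8.94). With the mean of a list, percentiles by tuft marker within Lgr5+ were 3.97 for the Lgr5 signature (1.96), 92.1 for the Notch pathway (98.2), 94.7 for group 2 innate lymphoid and mast cell markers (98.9) and 99.97 for regenerative genes (96.2). Within Lgr5- they were 99.6 for regenerative genes (95.6) and 2.32 for enterocyte markers (29.1). By Lgr5 they were 97.7 for Wnt targets (59.5) and 98.7 for the unfolded protein response (95.4) within tuft marker+, and 93.6 for dissociation stress (99.2) and 0.02 for myeloid markers (3.72) within tuft marker-. The cause was not tested.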

Other observations

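Single members of the immune cell lists stood apart from their lists. The antibody joining chain gene Jchain was higher with the tuft marker by at least 3.12 within Lgr5+ and 4.07 within Lgr5-. Il2rb, a cytokine receptor gene of T and NK cells, differed by 1.53 and 2.51. The IgE receptor gene Fcer1a differed by -1.32 within Lgr5+ and 0.91 within Lgr5-. Among IL-17RB pathway genes, the receptor partner gene Il17ra differed by 1.46 and 1.13, and the adaptor gene Traf3ip2 by -0.09 and -1.11. Among dissociation stress genes, the phosphatase gene Dusp1 differed by 1.38 and 2.11 and the immediate early gene Nr4a1 by 0.17 and 1.81. Among unfolded protein response genes, Ddit3 differed by -0.18 and -1.79 and the chaperone gene Hyou1 by -0.52 and -1.36. The interferon-induced gene Gbp2 was lower in Lgr5+ than in Lgr5- cells, at -1.29 within tuft marker+ and -1.39 within tuft marker-.

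By Lgr5, the IL-17RB pathway stood at 0.03 (60.8) within tuft marker+, turned to -0.13 by the authors' scaled values, and at 0.02 (52.5) within tuft marker-, turned to -0.09 by scaling to the median. Notch pathway genes stood at -0.03 (40.6), turned to 0.20 by scaling to the median, and at 0.04 (61.9), turned to -0.08 by the same scaling. Within tuft marker-, group 2 innate lymphoid and mast cell markers stood at 0.08 (48.4), turned to -0.09 after normexp. B and plasma cell markers stood at 0.06 (48.3) there, turned to -0.05 by scaling to the median. Erythroid markers stood at -0.01 (36.3), turned to 0.06 by the authors' scaled values.

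Above background on both tuft marker+ arrays and on neither tuft marker- array were 265 genes, and 229 the other way round. For Lgr5 these counts were 85 and 149. The 100 brightest spots held 31.9%, 28.1%, 33.9% and 29.6% of the signal in Lgr5+ tuft marker+, Lgr5+ tuft marker-, Lgr5- tuft marker+ and Lgr5- tuft marker- cells.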
